A study of Mus musculus with 59 samples.

How the data were processed

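The series holds 59 samples of mouse embryonic stem cells: 35 RNA libraries and 24 chromatin immunoprecipitation (ChIP) libraries. Per the labels, floxed DGCR8 and floxed Drosha cells were treated with 4OHT for 24, 48 or 96 h or left untreated (23 RNA libraries, 2 per group, 1 for Drosha 4OHT at 96 h). A further 12 RNA libraries came from parental cells (parental 1 and 2) and 4 Mettl3 knockout lines (1d1, 3xU, 1d2, 2c4d). Each was sampled at 37 °C and after 1 h at 42 °C. The ChIP libraries used streptavidin pulldown of biotin-tagged proteins, with formaldehyde or DSG crosslinking, in 4 sets: 6 libraries of DGCR8, Dicer, Drosha and inputs, 6 of METTL3 from 2 clones, 3 of DGCR8 in wild type and Mettl3 knockout cells, and 9 of DGCR8 and METTL3 at 37 °C and 42 °C with inputs at 37 °C only. The labels do not say whether parental 1 and 2 are different lines or whether the knockout lines were derived independently. Nor do they say whether METTL3 H4 and H5 of the heat set are different clones. Where any of these does not hold, n overstates the replication. In fits with the cell line as a block, parental 1 and parental 2 each counted as a line. Titles and source names conflicted in the floxed RNA set (4OHT replicate 1 and control replicate 2 at each time), in the METTL3 set (first precipitate and input of each clone) and in the heat ChIP set (METTL3 precipitates, DGCR8 and H4 inputs). Titles and column names were followed. Under the titles, every 4OHT library of the Drosha line had less Drosha RNA than every control, and every 4OHT library of the DGCR8 line had more Dgcr8 RNA. Also, 1 DGCR8 column was assigned to the formaldehyde precipitate by elimination.

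The deposited RNA tables hold read counts per gene, and the deposited ChIP tables hold read counts per 5 kb window. RNA was depleted of ribosomal RNA, per the labels' protocols; reads were aligned with Bowtie to mm10, per the submitters' processing notes. The version of the aligner, its options, the counting strand and the gene annotation were not given in the sources used here. The values were whole numbers without rescaling, so they were treated as raw counts. Totals per library, in units of 1e6 reads, ran from 9.58 to 12.6 for the floxed lines and from 7.10 to 13.6 for the heat RNA set. For ChIP they ran from 16.1 to 59.8 in the set with Dicer and Drosha, from 13.8 to 29.5 for METTL3, from 21.6 to 30.3 for the knockout set and from 20.4 to 86.3 for the heat set. Of 39017 gene identifiers, 37607 had a symbol and 1410 had none. Of 546202 windows, the 526765 on chromosomes 1 to 19 and X were used, and 30961 genes were placed on those chromosomes with a coordinate table. No genome sequence was at hand.

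Gene counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalisation, filterByExpr by group and Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. The DGCR8 line (14973 genes tested), the Drosha line (16262) and the heat set (15635) each had 1 fit with 1 coefficient per group, so that comparisons shared an estimate of the spread. Differences between the floxed lines came from a joint fit (16606 genes). Standard errors are those of the log2 fold change of the fit, and CPM values are TMM-scaled means ± SD, for Dgcr8 and Drosha in the floxed lines from the joint fit. The CPM of samples far from their group and of the milk protein genes are scaled to library totals alone. Fixed gene lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation and with fry beside it. "Over the list alone" means adjusted over the members of that list only. The p-values measure only the spread between these samples, which may be technical.

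METTL3 windows with a mean of at least 10 counts per library, and genes summed over the windows that overlap them, were tested in the same way. Conditions with 1 ChIP library had no test: the log2 ratio of CPM was taken with a pseudocount of 1 scaled to the smaller library, for windows or genes with at least 50 counts in the 2 libraries together. Its 95% intervals cover counting error only, and a ratio against 0 counts is a lower bound. Expression classes were quartiles of 13054 genes with at least 1 CPM in parental RNA at 37 °C (bounds 5.57, 19.4 and 58.6 CPM), genes under 1 CPM, and windows without a gene. Medians of lists were set against 10000 random lists of the same size from 20 bins of expression. A gene shares windows with its neighbours, so genes in 1 window share 1 value.

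Named genes followed a rule written before the data were examined. It took the targeted genes, up to 10 rising and 10 falling genes with the largest fold change among called genes with a mean log2 CPM of at least 2 and groups that did not overlap, and up to 4 members of each list by smallest p. For ChIP it took the 10 highest and 10 lowest genes with input at most 5 times the median window, the heat shock core genes, the targeted genes and 4 pluripotency genes. Genes in the text outside this rule were chosen after their values had been seen; they are mainly Mir17hg, Mir290a and the milk protein genes in libraries where the rule did not reach them. The comparisons, tests, lists and most alternatives were also fixed before the data were examined. Added afterwards were fits without mitochondrial genes, fits by a set of libraries with high or low Malat1, the heat-induced genes by block and by DESeq2, the top 1% of DGCR8 genes, other lactation genes, and correlations across genes. The limit of 50 counts was first 20 for windows in exploration.

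Whether RNA libraries pair was checked before the blocked calls were compared. Heat RNA libraries paired by cell line: deviations from the group means of the same line at both temperatures correlated at 0.476 to 0.742. Values with the cell line as a block therefore stand beside those results. Values with H4 or H5 as a block stand beside the METTL3 heat results, although pairing was not checked there. Replicate numbers of the floxed lines did not pair (-0.411, 0.284 and 0.232 in the DGCR8 line; -0.0396 and -0.11 in the Drosha line). The alternatives tried were DESeq2 1.42.0, RLE normalisation, no filter, a mean of at least 50 counts, only the compared groups, a replicate block, leaving out each library, window means of 5 or 25, a pseudocount of 5, a minimum of 100 counts, library size only, and scaling to windows without a gene. Descriptive steps ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9; random draws used seed 1.

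The tests were tested on simulated data in which 100 genes were changed 2-fold and 100 others 4-fold in each RNA comparison. At a 2-fold change the DGCR8 line gave back 61, 69 and 62 at 24, 48 and 96 h, the Drosha line 95, 95 and 80, the heat comparison 6 in parental and 39 in knockout cells, and knockout against parental 16 at 37 °C and 18 at 42 °C. At a 4-fold change the lowest of these was 79, for parental heat. For the interaction of heat and genotype it was 0 at 2-fold and 44 at 4-fold, so that comparison without a block could see only large differences. The simulations drew each library independently and fitted no block. They do not tell what the fits with the cell line as a block could see. The difference between the floxed lines gave back 34 at 2-fold at both 48 and 96 h, and 96 and 88 at 4-fold. The 96 h minus 24 h comparison gave back 18 at 2-fold and 90 at 4-fold in the DGCR8 line, and 61 and 97 in the Drosha line. Between 2 and 16 unchanged genes were called in each of these RNA simulations. In a like simulation of METTL3 genes after heat, 22 of 157 calls fell on unchanged genes.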

Results

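In mouse embryonic stem cells carrying floxed Drosha, the RNA of Drosha, the nuclease of the Microprocessor that excises microRNA hairpins from primary transcripts, fell from 85.1 ± 3.72 to 26.3 ± 4.02 CPM (TMM-scaled; mean ± SD, n = 2 and 2) after 24 h of 4-hydroxytamoxifen (4OHT). It stood at 25.7 ± 1.41 against 111 ± 0.138 at 48 h (n = 2 and 2), and at 24.2 (n = 1) against 117 ± 13.1 (n = 2) at 96 h. In the floxed Dgcr8 line, the RNA of Dgcr8, the hairpin-binding partner of Drosha, did not fall but rose, from 105 ± 0.0265 to 250 ± 3.51 CPM at 24 h, from 141 ± 6.08 to 271 ± 16.6 at 48 h and from 126 ± 7.65 to 256 ± 46.8 at 96 h (n = 2 and 2 each). Dgcr8 RNA also rose in the Drosha line, from 78.8 ± 1.14 to 282 ± 2.42 at 24 h, from 102 ± 1.98 to 369 ± 19.6 at 48 h and from 114 ± 4.08 to 297 (n = 1) at 96 h. Drosha RNA did not pass the test in the DGCR8 line (log2 fold changes 0.11, -0.03 and 0.09; adjusted p = 0.997, 0.95 and 0.736). The counts are per whole gene, so the loss of the floxed Dgcr8 exons themselves could not be measured. No line without floxed alleles was treated with 4OHT, so effects of 4OHT itself were not separated from those of gene loss.

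**Figure D1:**
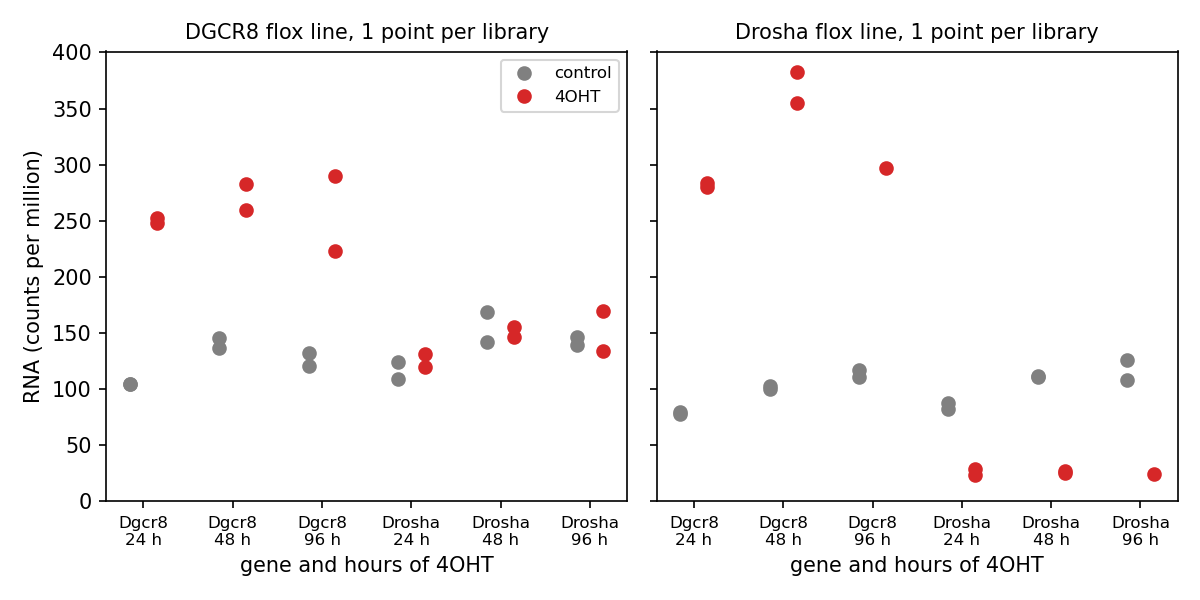
Dgcr8 and Drosha RNA in CPM, 1 point per library, by hours of 4OHT in both floxed lines. Drosha fell from 85.1 ± 3.72 to 26.3 ± 4.02 at 24 h in its own line, while Dgcr8 rose from 105 ± 0.0265 to 250 ± 3.51 in the DGCR8 line (mean ± SD, n = 2 and 2).

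After 24 h of 4OHT in the DGCR8 line, the transcripts that carry microRNA hairpins rose most (n = 2 and 2 throughout). Mir17hg, the host transcript of the oncogenic miR-17-92 cluster, rose by a log2 fold change of 2.22 ± 0.18 (± SE, adjusted p = 0.0014), from 73.5 ± 17.8 to 342 ± 17.9 CPM. The hairpin gene Mir19b-1, at the edge of the annotated Mir17hg span, rose by 3.55 ± 0.36 (adjusted p = 0.00319). Mir290a, from the cluster that makes the main embryonic stem cell microRNAs, rose by 2.63 ± 0.34 (adjusted p = 0.0139) and Mir22hg, the host of miR-22, by 1.83 ± 0.27 (adjusted p = 0.0395). Dgcr8, whose own mRNA holds a hairpin, rose by 1.27 ± 0.13 (adjusted p = 0.00319), and so did Egr1, an immediate early transcription factor, by 1.16 ± 0.17 (adjusted p = 0.0318). As a list, 12 of 15 miRNA host transcripts were higher, 3 of them called, or 7 adjusted over the list alone (camera adjusted p = 6.23e-23; adjusted p = 0.00246 with an estimated correlation). Of 14973 genes, 16 rose and 0 fell, 13 of them over 2-fold; 780 had an unadjusted p below 0.05, and 749 would by chance. DESeq2 called 29. The call depended on every library: it fell to 1 without control replicate 1, 1 without control replicate 2, 4 without 4OHT replicate 1 and 4 without 4OHT replicate 2.

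At 48 h in the DGCR8 line, targets of p53 were among the genes that rose (n = 2 and 2). Perp, a p53 target in apoptosis, rose by 1.10 ± 0.13 (adjusted p = 0.00343), from 30.3 ± 2.08 to 64.8 ± 1.88 CPM, Btg2, which slows proliferation, by 0.91 ± 0.18 (adjusted p = 0.0303), and Cdkn1a, the cell cycle inhibitor p21, by 1.08 ± 0.22 (adjusted p = 0.0374). Ago1, an Argonaute loaded with microRNA, and Tnrc6a, which binds Argonaute, rose by 1.05 ± 0.18 and 1.06 ± 0.17 (adjusted p = 0.0176 for both). Klf2, a naive pluripotency factor, rose by 1.08 ± 0.17 (adjusted p = 0.015). Cry1, a clock repressor, fell by 0.91 ± 0.11 (adjusted p = 0.00513), from 70.3 ± 0.221 to 37.4 ± 0.404 CPM. Spry1, an inhibitor of FGF signalling, fell by 1.07 ± 0.16 (adjusted p = 0.013). Among 20 p53 targets, 17 were higher, 6 called and 10 over the list alone (camera adjusted p = 1.32e-09; adjusted p = 0.00965 with an estimated correlation). Of 23 miR-290 family targets, 19 were higher, 3 rose and 1 fell, or 12 and 1 over the list alone (camera adjusted p = 4.04e-07; adjusted p = 0.00986 with an estimated correlation). All 8 neuroectoderm markers were higher, Sox1 being called (0.72 ± 0.15, adjusted p = 0.0457) and 4 passing over the list alone; the list call (camera adjusted p = 0.000103) was lost with an estimated correlation (adjusted p = 0.185 with an estimated correlation). In all 185 genes rose and 36 fell, 72 and 9 of them over 2-fold. DESeq2 called 338. Without control replicate 1 the total was 27, without control replicate 2 16, without 4OHT replicate 1 18 and without 4OHT replicate 2 15.

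At 96 h miR-290 family targets were higher in the DGCR8 line (n = 2 and 2). Rbl2, a pocket protein repressed by the miR-290 family, rose by 1.62 ± 0.18 (adjusted p = 0.000683), from 9.50 ± 0.0507 to 29.3 ± 1.61 CPM, and Tgfbr2, the type II TGF-beta receptor, by 1.95 ± 0.29 (adjusted p = 0.00252). Map2, a neuronal microtubule protein, rose by 1.16 ± 0.19 (adjusted p = 0.00338) and Sox1 by 1.05 ± 0.15 (adjusted p = 0.00204). Irf1, of the interferon response, rose by 1.00 ± 0.14 (adjusted p = 0.00187). Dnmt3l, the cofactor of de novo DNA methylation, fell by 1.03 ± 0.11 (adjusted p = 0.00053), from 73.5 ± 1.77 to 35.9 ± 1.99 CPM, Lin28a, which blocks let-7, fell by 0.84 ± 0.17 (adjusted p = 0.00846), and Bnip3, a hypoxia-induced mitophagy receptor, fell by 2.16 ± 0.35 (adjusted p = 0.00338). Of 23 miR-290 family targets, 21 were higher, 12 rising and 1 falling, or 13 and 1 over the list alone (camera adjusted p = 1.55e-07; adjusted p = 0.0151 with an estimated correlation). Among 18 glycolysis genes, 14 were lower, 6 called and 9 over the list alone (camera adjusted p = 0.000487), a call lost when the correlation was estimated (adjusted p = 0.0588 with an estimated correlation). Ribosomal protein genes (69 of 86 lower, 12 called and 12 over the list alone; camera adjusted p = 4.37e-07) also lost their call (adjusted p = 0.438 with an estimated correlation). In all 1235 genes rose and 782 fell, 491 and 182 of them over 2-fold. DESeq2 called 1823. The treated libraries stood far apart: mt-Rnr2 held 27.1% and 9.55% of their counts, and chi-squared per gene was 139 against 4.48 to 16.2 in the other floxed groups. The total was 459 without control replicate 1, 401 without control replicate 2 and 0 when the 4 libraries of this comparison were fitted alone. The test of the 96 h effect minus the 24 h effect called 25 genes up and 2 down, among them Rbl2 (1.71 ± 0.25, adjusted p = 0.0372) and Dnmt3l (-1.01 ± 0.15, adjusted p = 0.042). That total was 0 without any of the 4 libraries of 24 h or either control of 96 h, 108 without 4OHT 96 h replicate 1 and 512 without 4OHT 96 h replicate 2.

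In the Drosha line at 24 h, primary microRNA transcripts again led (n = 2 and 2). Mir19b-1 rose by 3.92 ± 0.36 (adjusted p = 7.48e-05), Mir22hg by 2.89 ± 0.19 (adjusted p = 1.96e-06), Mir17hg by 2.16 ± 0.18 (adjusted p = 2.34e-05), from 57.4 ± 1.58 to 257 ± 21.1 CPM, and Mirg, a transcript of the imprinted Dlk1-Dio3 locus packed with microRNAs, by 1.82 ± 0.16 (adjusted p = 4.78e-05). Rtl1, an imprinted retrotransposon-derived gene of that locus, rose by 3.06 ± 0.46 (adjusted p = 0.00812). Drosha fell by 1.68 ± 0.12 (adjusted p = 6.85e-06), Dgcr8 rose by 1.84 ± 0.09 (adjusted p = 3.46e-08) and Snord22, a small nucleolar RNA, fell by 0.95 ± 0.17 (adjusted p = 0.0439). Of 18 host transcripts, 16 were higher, 4 called and 9 over the list alone (camera adjusted p = 2.13e-31; adjusted p = 0.0202 with an estimated correlation). All 55 histone genes were lower, 0 called and 11 over the list alone; their list call (camera adjusted p = 9.52e-19) was lost (adjusted p = 0.178 with an estimated correlation). Of 16262 genes, 25 rose and 5 fell, 24 and 4 over 2-fold; 1816 had an unadjusted p below 0.05, 813 by chance. DESeq2 called 41. Without control replicate 1 the total was 11, without control replicate 2 9, without 4OHT replicate 1 47 and without 4OHT replicate 2 16. Fitting these 4 libraries alone gave 748.

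At 48 h in the Drosha line, p53 targets were among the genes that rose (n = 2 and 2). Ccng1, a p53 target that acts on the p53 regulator Mdm2, rose by 0.75 ± 0.09 (adjusted p = 0.000697), from 400 ± 14.3 to 670 ± 56.7 CPM, Btg2 by 1.08 ± 0.10 (adjusted p = 6.76e-05), Trp53inp1, a p53-induced stress protein, by 0.70 ± 0.10 (adjusted p = 0.00259) and Cdkn1a by 0.81 ± 0.15 (adjusted p = 0.0102). Lefty1, a Nodal antagonist and miR-290 family target, rose by 0.72 ± 0.16 (adjusted p = 0.0257) and Pdgfra, a receptor of primitive endoderm, by 0.75 ± 0.16 (adjusted p = 0.0191). Chac1, a stress-induced glutathione-degrading enzyme, fell by 1.12 ± 0.20 (adjusted p = 0.00751) and Atf4, its activator, fell by 0.50 ± 0.10 (adjusted p = 0.0124). Among 21 p53 targets 18 were higher, 9 called and 13 over the list alone (camera adjusted p = 1.76e-16; adjusted p = 0.00519 with an estimated correlation). Endoderm markers (14 of 15 higher, 2 called and 5 over the list alone; camera adjusted p = 0.00305) lost their call (adjusted p = 0.435 with an estimated correlation). In all 398 genes rose and 60 fell, 97 and 10 of them over 2-fold. DESeq2 called 370. Without control replicate 1 the total was 47, without control replicate 2 126, without 4OHT replicate 1 198 and without 4OHT replicate 2 987.

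At 96 h, with 1 treated library against 2 controls in the Drosha line, p53 targets were again among the genes that rose. Ccng1 rose by 1.65 ± 0.11 (adjusted p = 1.14e-06), to 1130 from 361 ± 17.9 CPM, Trp53inp1 by 1.52 ± 0.12 (adjusted p = 3.78e-06) and Cdkn1a by 1.48 ± 0.18 (adjusted p = 8.62e-05). Pou3f1 and Dnmt3b, genes of the primed state, fell by 1.41 ± 0.21 and 1.09 ± 0.14 (adjusted p = 0.000363 and 0.000145), while Cubn, an endocytic receptor of extraembryonic endoderm, rose by 0.87 ± 0.14 (adjusted p = 0.000709). Vegfa, the angiogenic growth factor, fell by 1.06 ± 0.18 (adjusted p = 0.000792) and the mitochondrial gene mt-Nd1 rose by 1.26 ± 0.18 (adjusted p = 0.000251). Of 24 miR-290 family targets 20 were higher, 13 called and 13 over the list alone (camera adjusted p = 5.91e-07), a call lost when the correlation was estimated (adjusted p = 0.104 with an estimated correlation). The p53 list kept its call: 9 rose and 3 fell, or 12 and 4 over the list alone (camera adjusted p = 1.22e-08; adjusted p = 0.0247 with an estimated correlation). In all 2066 genes rose and 1788 fell, 579 and 386 of them over 2-fold. DESeq2 called 2998. The spread within the treated group could not be measured, and the test borrowed it from the other groups of this line. The treated pair of the DGCR8 line at 96 h varied more (chi-squared per gene 139), and the lone Drosha library held a similarly high share of mt-Rnr2 (21.3%), so the borrowed spread could be too small and these counts too high. The 96 h effect exceeded the 24 h effect in 1029 genes and lay below it in 851, with Serpinb9b, a serine protease inhibitor, at 2.69 ± 0.21 (adjusted p = 3.89e-05) and Vegfa at -1.24 ± 0.21 (adjusted p = 0.00386). That total was 642 without control 24 h replicate 1, 773 without control 24 h replicate 2, 651 without 4OHT 24 h replicate 1 and 817 without 4OHT 24 h replicate 2.

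The responses of the floxed lines shared genes at each time. Since both lines received 4OHT and no line without floxed alleles did, shared effects of the treatment itself were not separated from those of gene loss. Both lines raised 10 of the same genes at 24 h (0.0271 by chance), 103 at 48 h (4.98 by chance) and 708 at 96 h (173 by chance), and lowered 5 at 48 h (0.146 by chance) and 390 at 96 h (94.6 by chance). Of genes called in both lines, 10 of 10, 108 of 108 and 1098 of 1105 moved the same way, and across 10769 genes the effects correlated at 0.45, 0.55 and 0.58 (Pearson, across genes, which are not independent replicates). At 96 h DGCR8 4OHT replicate 1 and the lone Drosha 4OHT library both held a high share of mt-Rnr2 (27.1% and 21.3%), and the difference between the DGCR8 replicates correlated at 0.364 across genes with the Drosha effect, so part of the overlap at 96 h could come from the libraries. At 48 h the test of the difference between the lines called only Drosha itself (2.07 ± 0.19, adjusted p = 5.72e-05), with 857 genes below an unadjusted p of 0.05 against 830 by chance. In simulation this test gave back only 34 of 100 genes changed 2-fold, so it could miss such differences. DESeq2 called 8. At 96 h it called 19 genes higher and 11 lower in the DGCR8 line. Zic2, a neural transcription factor, differed by 1.98 ± 0.26 (adjusted p = 0.00495) and Egr1 by 1.76 ± 0.26 (adjusted p = 0.0112), whereas the endoderm genes Cubn and Dab2 differed by -1.31 ± 0.25 and -1.35 ± 0.26 (adjusted p = 0.0447 and 0.0471; n = 2, 2, 1 and 2). The 96 h total was 2 without DGCR8 control replicate 1, 1 without DGCR8 control replicate 2, 1876 without DGCR8 4OHT replicate 1, 16 without DGCR8 4OHT replicate 2, 4 without Drosha control replicate 1 and 4 without Drosha control replicate 2, and 0 when only the compared groups were fitted.

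**Figure D2:**
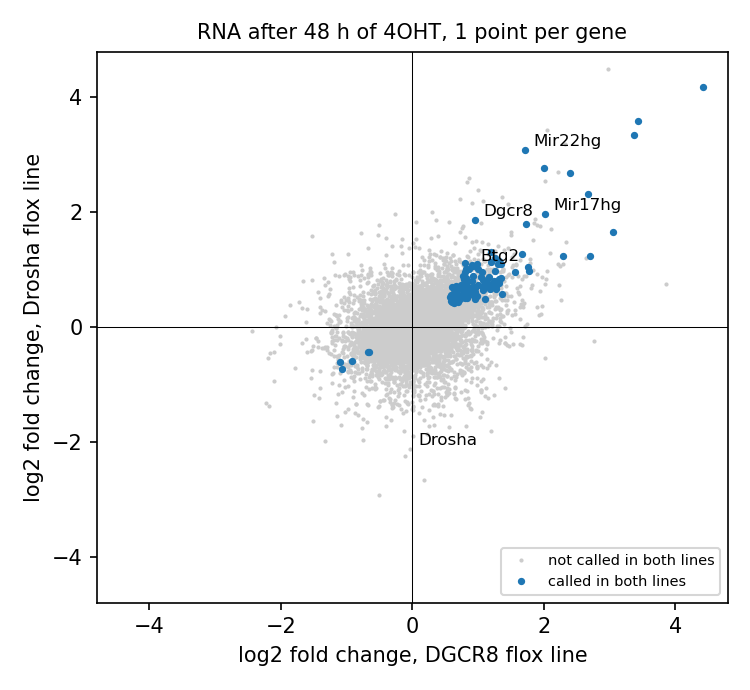
Log2 fold change at 48 h of 4OHT in the Drosha line against the DGCR8 line, 1 point per gene, with the genes called in both lines marked. Both lines raised 103 of the same genes and lowered 5; the effects correlated at 0.55 across 10769 genes.

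Parental cells held at 42 °C for 1 h raised the inducible HSP70 genes (n = 2 and 2). Hspa1a rose from 0.861 ± 0.288 to 204 ± 58.4 CPM (log2 fold change 7.86 ± 0.41, adjusted p = 1.78e-06) and its near-identical copy Hspa1b from 2.60 ± 1.31 to 349 ± 79.9 (7.07 ± 0.41, adjusted p = 2.96e-06), so reads may be shared between them. Zfp941, a zinc finger gene, fell by 2.09 ± 0.25 (adjusted p = 0.0101). Dnajb1, the HSP40 co-chaperone, stood at 189 ± 27.5 against 33.9 ± 6.36 CPM and did not pass without a block (2.48 ± 0.43, adjusted p = 0.147), but passed by DESeq2 and with the cell line as a block (blocked adjusted p = 5.78e-06). Fgf4, the autocrine differentiation factor of these cells, passed with the block but not without it (-1.10 ± 0.25, adjusted p = 0.568; blocked adjusted p = 0.00125). All 8 heat shock core genes were higher, 2 called and 4 over the list alone (camera adjusted p = 4.97e-66). Among 19 immediate early genes 14 were higher, 0 called and 3 over the list alone (camera adjusted p = 1.37e-11; adjusted p = 0.0251 with an estimated correlation), and 46 of 53 histone genes were higher, 0 called and 0 over the list alone (camera adjusted p = 5.04e-17; adjusted p = 0.0251 with an estimated correlation). With the cell line as a block 3 immediate early genes, among them Zfp36 (blocked adjusted p = 0.000489), and 6 histone genes were called higher, but neither list kept its call (adjusted p = 0.147 and 0.115 with an estimated correlation). Of 15635 genes, 2 rose and 1 fell; 425 had an unadjusted p below 0.05, fewer than the 782 of chance. DESeq2 called 31. With the cell line as a block, 69 rose and 50 fell.

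In the Mettl3 knockout lines, targeted in the catalytic subunit of the m6A writer, the same chaperones rose (n = 4 and 4). Hspa1a went from 1.05 ± 0.353 to 199 ± 34.3 CPM (7.53 ± 0.29, adjusted p = 3.63e-08), Hspa1b from 4.36 ± 1.19 to 396 ± 26.7 (6.51 ± 0.28, adjusted p = 7.93e-08) and Dnajb1 from 56.0 ± 22.5 to 261 ± 79.1 (2.22 ± 0.30, adjusted p = 0.00721). Fos, an immediate early factor, rose by 2.82 ± 0.43 (adjusted p = 0.0204) and Hist1h1t, a testis linker histone, by 3.18 ± 0.36 (adjusted p = 0.00206). Foxd3, which maintains pluripotency, fell by 1.82 ± 0.29 (adjusted p = 0.0286) and Lefty1 fell by 1.48 ± 0.25 (adjusted p = 0.0338). The chaperone list was higher in 27 of 30 genes, 6 called and 10 over the list alone (camera adjusted p = 8.49e-55; adjusted p = 0.000242 with an estimated correlation), and 47 of 53 histone genes were higher, 2 called and 11 over the list alone (camera adjusted p = 4.39e-29; adjusted p = 0.00867 with an estimated correlation). With the cell line as a block 15 chaperones and 21 histone genes were called higher. In all 26 genes rose and 3 fell, 605 and 453 with the cell line as a block. DESeq2 called 115. At 37 °C the total was 14 without line 1d1, 17 without 3xU, 14 without 1d2 and 17 without 2c4d; at 42 °C it was 16 without 1d1, 15 without 3xU and 15 without 2c4d. The heat effect in knockout minus parental cells called 0 genes (208 below an unadjusted p of 0.05; 8 by DESeq2; 2 with the block, both lower) and no list. With the block 2 lists were called, unfolded protein response genes (11 of 18 higher) and histone genes (29 of 53 higher), each at a camera adjusted p = 0.0433 and each lost when the correlation was estimated (adjusted p = 0.777 and 0.885 with an estimated correlation). Whether the RNA response to heat differs between them was left open.

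At 37 °C the knockout lines held 30.1 ± 7.93 CPM of Mettl3 RNA against 70.3 ± 1.60 in the parental libraries (-1.23 ± 0.25, adjusted p = 0.0439, n = 4 and 2). The m6A readers Ythdc1 and Ythdf2 were higher, Ythdc1 at 413 ± 38.1 against 176 ± 6.22 CPM (1.23 ± 0.18, adjusted p = 0.0171) and Ythdf2 at 285 ± 34.5 against 150 ± 21.9 (0.93 ± 0.18, adjusted p = 0.0425). Genes of primitive endoderm were lower: the transcription factors Gata4 (0.412 ± 0.218 against 6.08 ± 0.117 CPM; -3.81 ± 0.42, adjusted p = 0.00426) and Gata6 (-3.16 ± 0.48, adjusted p = 0.0171), and the receptor Pdgfra (1.16 ± 0.299 against 10.4 ± 3.19 CPM; -3.14 ± 0.47, adjusted p = 0.0171). Tex15, a germline gene of transposon silencing, was lower at 19.7 ± 5.05 against 148 ± 1.02 CPM (-2.91 ± 0.33, adjusted p = 0.00426), and Fat2, an atypical cadherin, higher at 24.1 ± 5.81 against 2.70 ± 0.914 (3.15 ± 0.32, adjusted p = 0.00426). Endoderm markers were lower in 12 of 14, 5 called and 9 over the list alone (camera adjusted p = 8.16e-13; adjusted p = 0.0272 with an estimated correlation). In all 65 genes were higher and 76 lower, and 2500 had an unadjusted p below 0.05. DESeq2 called 779. The total was 0 without parental replicate 1, 0 without parental replicate 2, 26 without 3xU, 16 without 1d2 and 35 without 2c4d, 4 when only the compared groups were fitted, and 791 with the Malat1 library set as a block.

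**Figure D3:**
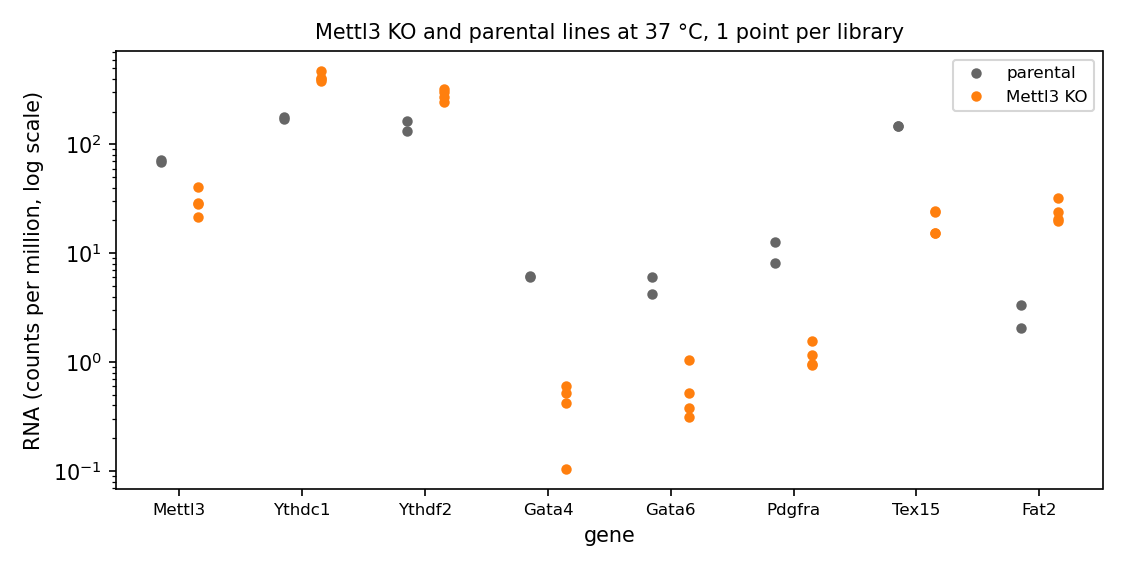
RNA of 8 genes at 37 °C in CPM on a log scale, 1 point per library, in parental and Mettl3 knockout cells. Ythdc1 stood at 413 ± 38.1 against 176 ± 6.22 and Gata4 at 0.412 ± 0.218 against 6.08 ± 0.117 (mean ± SD, n = 4 and 2).

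After heat the difference between the knockout lines and the parental libraries kept many of these genes (n = 4 and 2). Fat2 was higher by 4.36 ± 0.37 (adjusted p = 0.000542) and Ythdf2 by 1.20 ± 0.19 (adjusted p = 0.0301), whereas Tex15 (-2.76 ± 0.33, adjusted p = 0.0116), Gata4 (-2.47 ± 0.40, adjusted p = 0.0324) and Pdgfra (-2.78 ± 0.47, adjusted p = 0.0329) were lower. Mettl3 itself, at 28.8 ± 6.19 against 62.6 ± 3.17 CPM, did not pass (-1.12 ± 0.25, adjusted p = 0.0632). With the Malat1 library set as a block, an alternative added after the sets were seen, it passed (adjusted p = 0.0242) and the total was 738. Of the calls at 37 °C, 32 higher and 37 lower genes were called again, and endoderm markers were lower in 12 of 14, 4 called and 9 over the list alone (camera adjusted p = 8.16e-13; adjusted p = 0.0332 with an estimated correlation). In all 52 genes were higher and 48 lower, with 2520 below an unadjusted p of 0.05 and 753 called by DESeq2. The total was 1 without parental replicate 1, 0 without parental replicate 2, 55 without 1d1, 1 without 3xU, 6 without 1d2 and 26 without 2c4d, and 1 when only the compared groups were fitted.

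DGCR8 precipitated from chromatin crosslinked with DSG lay most over microRNA genes (1 library against 1 input, so no test was made). The chromosome 7 window holding Mir293, Mir294 and Mir295 gave 27978 counts against 80 in input, a log2 ratio of 8.31 (95% interval 8.02 to 8.67). Mir17hg on chromosome 14 followed at 6.27 (6.03 to 6.55; 10828 against 128), then the window shared by Mir290a to Mir292 at 5.30, and the window of Mirlet7a-1 and Mirlet7d, hairpins of the differentiation-linked let-7 family, at 5.28. Hspa8, the constitutive HSP70, stood at 2.24, and the pluripotency factors Pou5f1 and Sox2 at 1.56 and 1.40. With formaldehyde alone the ratios were smaller, 4.20 at Mir293 (1142 against 80 counts), 2.80 at Mir290a and 1.64 at Mir17hg. The lowest formaldehyde ratio fell on the 5S ribosomal RNA genes of chromosome 8, n-R5s141 at -3.37. As lists, the miRNA hosts had a median of 1.155 with DSG, above 100% of random lists of equal size and expression, and ribosomal protein genes 1.122, with 84 of 89 above 0. Relative to windows without a gene, the DSG medians were -0.469, -0.455, -0.305 and 0.040 from the lowest to the highest expression quartile, so only the most expressed genes reached their level. Windows without a gene themselves lay at 0.407. Over 2-fold stood 2736 genes and under it 1184 of 28984 for DSG, and 849 and 324 of 28292 for formaldehyde.

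Drosha, crosslinked with DSG, shared the microRNA windows and added milk protein genes (1 library against 1 input). Mir293 reached 6.57 (6.28 to 6.95; 4065 against 78 counts), Mirlet7d 4.00 and Mir17hg 3.91, with Hspa8 at 1.90 and Sox2 at 1.68. Its highest ratio, 7.70 (7.21 to 8.49; 2647 against 22 counts), lay on chromosome 5 at Csn2, which encodes beta-casein. Csn1s1, Csn1s2a, Csn1s2b and Csn3, the other caseins, gave 5.29, 5.08, 4.65 and 4.51, and Wap, a whey protein, 4.98. Dicer, the cytoplasmic nuclease that matures precursors, stood at -0.96 over Mir295 and -0.27 over Mir17hg. Across genes, which are not independent replicates, the DGCR8 DSG ratio correlated with that of Drosha at 0.673 (12717 genes) and with that of Dicer at -0.148 (Pearson). In the Drosha library 2149 genes stood over 2-fold and 2729 under it of 26555, against 44 and 24 of 28135 for Dicer.

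**Figure D4:**
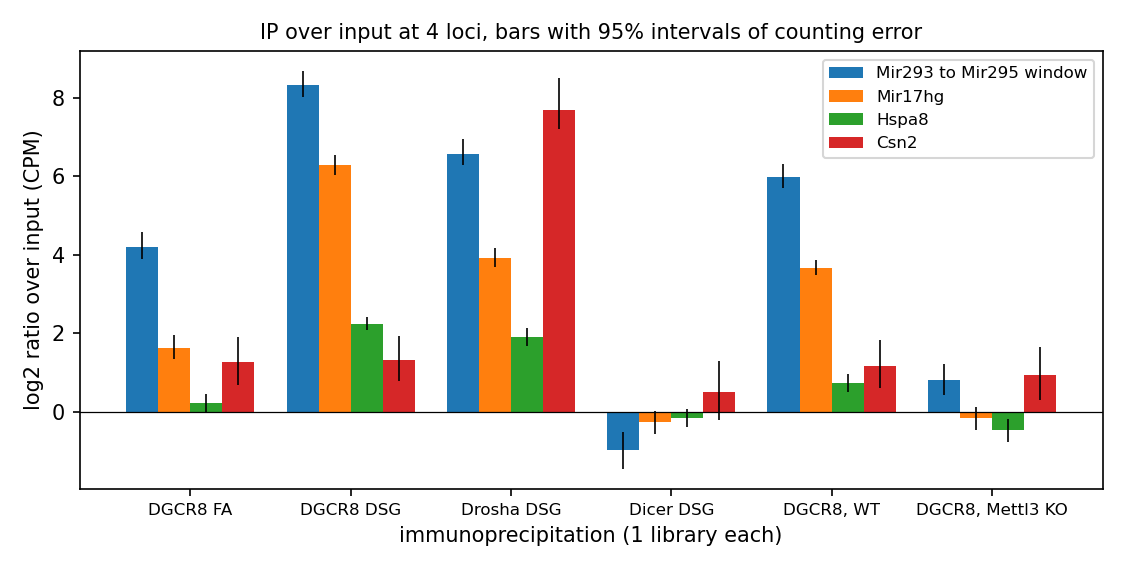
Log2 ratio of precipitate over input with 95% counting intervals at 4 loci in 6 precipitates. DGCR8 with DSG reached 8.31 at the Mir293 window and 6.27 at Mir17hg, and Drosha 7.70 at Csn2 (1 library each).

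METTL3, the m6A methyltransferase, was precipitated from 2 clones (4 precipitates, 2 inputs). The 10 windows with the largest gains over input included the chromosome 17 window shared by Mog, a myelin gene, and Zfp57, a keeper of imprints (4.01 ± 0.32, adjusted p = 1.39e-22), that of Lncenc1, a long noncoding RNA of naive cells, on chromosome 13 (3.95 ± 0.33, adjusted p = 4.68e-21), and that of Hspa8 on chromosome 9 (3.53 ± 0.29, adjusted p = 2.22e-22). The Hspa8 window runs from base 40805001 to 40810000 and the Hspa8 span ends at 40805202, so this window lies mostly outside the gene. Among the same 10, windows of Resf1, a retroelement silencing factor, and Eef1a1, the translation elongation factor, gained 3.91 ± 0.29 and 3.60 ± 0.28. The 5S ribosomal RNA genes of chromosome 8 lost most (-4.82 ± 0.27, adjusted p = 3.27e-36). Pluripotency genes had list medians of 0.372, 0.520, 0.802 and 0.267 in the 4 precipitates (n = 26 genes), whereas 14 of 14 mesoderm markers lay below 0 in each, with medians of -1.184, -1.178, -0.986 and -0.942. Of 477127 windows, 19741 were higher and 59720 lower (edgeR, adjusted p < 0.05), 6828 and 23562 of them over 2-fold. The split depended on normalisation: with library size only, 63700 were higher and 40780 lower. Leaving out the input of clone 2 gave 52359 and leaving out that of clone 1 gave 40232, each with 1 input left. In the fit with all libraries, genes overlapped 56.9% of the higher and 66.4% of the lower windows, against 47.0% of all windows tested. Over 2-fold, they overlapped 50.4% of the higher and 72.2% of the lower windows. Higher windows were thus less often in genes than lower ones.

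In the Mettl3 knockout, DGCR8 was lower over its main microRNA loci (1 precipitate against 1). In wild type cells the Mir293 window gave 6816 counts against 93 in input (5.98, 5.70 to 6.30), Mir290a 4.17 and Mir17hg 3.67 (3478 against 236). In the knockout precipitate the Mir293 window held 135 counts, a log2 ratio to the wild type precipitate of -5.16 (-5.43 to -4.93), Mir290a 99 against 2218 (-3.99) and Mir17hg 173 against 3478 (-3.84). Ypel4, a gene of the yippee family, stood at -3.80, Nlrp12, an inflammasome gene whose span covers the miR-290 cluster, at -3.78, and Hspa8 at -1.20. The miRNA host list had a median of -0.504, lower than 100% of random lists (percentile 0), with 17 of 22 genes below 0 and 7 under 2-fold. Of 89 ribosomal protein genes, 81 lay below 0 (median -0.414). The top expression quartile moved little, -0.055 relative to windows without a gene. But the wild type precipitate itself stood there at -0.020 over input, -0.204 relative to windows without a gene. This measure thus had no enrichment to lose. In all 54 genes stood over 2-fold and 235 under it of 28604. With 1 library of each kind, a difference in precipitation between these libraries could not be separated from one in binding.

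After 1 h at 42 °C DGCR8 lay over heat shock genes (1 precipitate against 1). The series holds no input at 42 °C, so a change in input was not separated from one in the precipitate. Hspa1b went from 66 to 5558 counts (log2 ratio 4.42, 4.09 to 4.81), Hspa1a from 130 to 7788 (3.94), and Hsph1, the HSP110 chaperone, from 561 to 20955 (3.26). Dnajb1 stood at 2.32, Hspb1, the small heat shock protein HSP27, at 1.77, Hsp90aa1, the inducible HSP90, at 1.07 and Bag3, an HSP70 nucleotide exchange factor, at 0.42. Among the lowest ratios were Snora81, a small nucleolar RNA that guides pseudouridine formation, at -4.35 (247 against 1316 counts), Snhg3, the host of others, at -4.24, and Snora3 at -3.62. Pou5f1 stood at -2.16, all 26 pluripotency genes lay below 0 (median -1.650), and 84 of 89 ribosomal protein genes did (median -2.191). The 8 heat shock core genes had a median of 2.044, above 100% of random lists. At 37 °C the precipitate had stood 0.708 above windows without a gene in the top expression quartile, with Mir293 at 9.23 (25969 against 129 counts); the 42 °C over 37 °C ratio in that quartile was -0.948 relative to windows without a gene. In all 1931 genes stood over 2-fold and 3208 under it of 29492, and the largest ratios of all were lower bounds, such as that of the pheromone receptor gene Vmn1r197 (182 against 0 counts).

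METTL3 also lay over heat shock genes at 42 °C (precipitates H4 and H5 at each temperature, n = 2 and 2). Hspa1a gained 9.13 ± 0.37 (adjusted p = 0.0159), Hspa1b 9.01 ± 0.33 (adjusted p = 0.0159), Hsph1 3.98 ± 0.27 (adjusted p = 0.0386) and Dnajb1 3.42 ± 0.17 (adjusted p = 0.0159). Snora81 changed by -2.29 ± 0.13 (adjusted p = 0.028) and Rps6, the ribosomal protein phosphorylated by S6 kinase, by -1.97 ± 0.13 (adjusted p = 0.0362). Sox2 and Klf2 did not pass without a block but did with H4 or H5 as a block (blocked -2.64 and -2.73, adjusted p = 5.85e-64 and 9.39e-69), as did the Mir293 window (-2.17, adjusted p = 9.58e-28). Their blocked standard errors (0.086, 0.082 and 0.152) were far below the unblocked ones (0.705, 0.527 and 0.332). The Mir293 window went from 25.4 to 3.43 CPM in H4 and from 19.7 to 6.39 in H5. With only 2 pairs, the blocked p-values may be too small and the blocked counts too high. All 8 heat shock core genes were higher, 4 called, 8 with the block and 7 over the list alone. With no input at 42 °C, a change in input at these genes was not separated from one in the precipitate. Input at 37 °C exceeded the limit of 5 times the median window at all 8, from 5.16 at Hsph1 to 15.2 at Dnajb1. It did so too at Sox2 (7.89) and Klf2 (16.8). All 26 pluripotency genes were lower, 0 called, 20 with the block and 14 over the list alone. Of 89 ribosomal protein genes 87 were lower, 3 called, 82 with the block and 74 over the list alone. Of 30036 genes 7 rose and 9 fell, 2096 and 5224 with the block; 5155 had an unadjusted p below 0.05, and DESeq2 called 58 up and 1525 down. Without the H4 library at 37 °C the total was 0, without H5 at 37 °C 0, without H4 at 42 °C 5 and without H5 at 42 °C 9. Of 495095 windows 0 were called (smallest adjusted p = 0.0582; 33024 below an unadjusted p of 0.05), against 5571 by DESeq2 and 1177 up and 9091 down with the block; the call was 976 without H4 at 37 °C, 351 without H4 at 42 °C, 1676 without H5 at 37 °C and 892 without H5 at 42 °C.

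**Figure D5:**
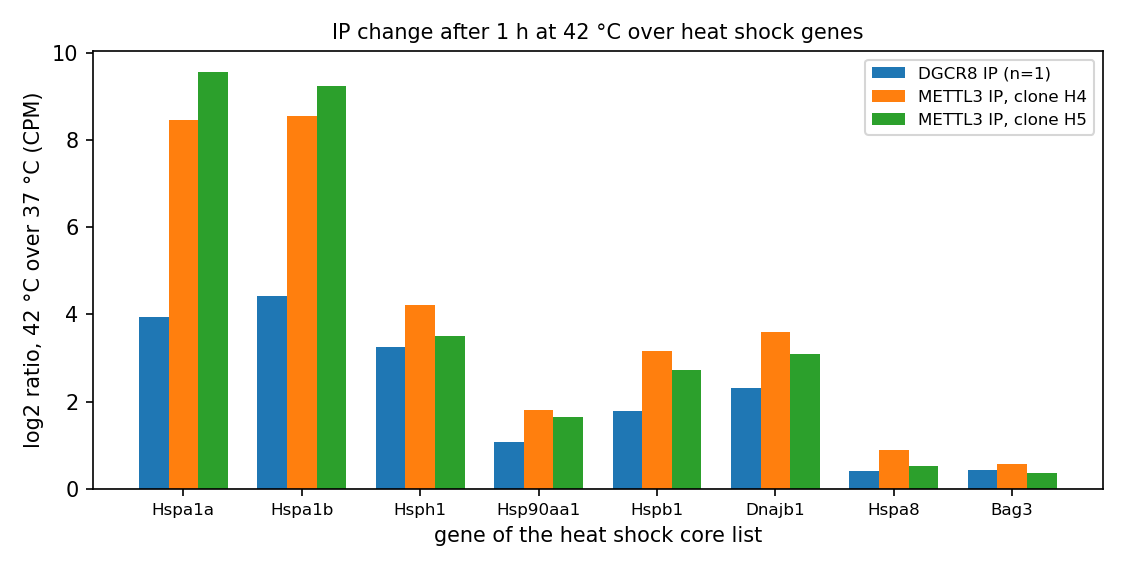
Log2 ratio of the 42 °C over the 37 °C precipitate at 8 heat shock core genes for DGCR8 and for METTL3 precipitates H4 and H5. The list medians were 2.044, 3.373 and 2.906 (1 library against 1 each).

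Which heat-induced genes were taken decided how far the precipitates followed them. For Hspa1a and Hspa1b, the only genes called higher in parental RNA by edgeR without a block, the median ratios were 4.18 for DGCR8, 8.51 for METTL3 H4 and 9.40 for H5. For 59 genes that rose with the cell line as a block, they were -0.349, -0.349 and -0.123, above 99.1%, 85.4% and 98.7% of random lists. For 20 genes that rose by DESeq2, they were -0.769, -0.536 and -0.043, above 16.3%, 16.2% and 98.0% of random lists. Chaperones as a list had medians of 0.323, 0.684 and 0.436, ribosomal protein genes -2.191, -1.443 and -0.927. Relative to windows without a gene, the top expression quartile stood at -0.429 in H4 and -0.257 in H5.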

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

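The tests of an exchange of libraries, of Microprocessor cleavage, of a property of the 96 h libraries and of the heat splits were chosen only after the result was seen; the tests of the milk protein genes and of a replicate further along the response were written down before their values were seen. A single sample stood far from the other 3 of its group in 6 of 97 groups of values, where about 4.85 would by chance (1 in 20). All 6 lay in the Mettl3 knockout lines, the only RNA groups with 4 libraries, so no other RNA group could be flagged. The ratio of the gap to the range is given first. At 37 °C A4galt was highest in 2c4d (0.939; 76.2 against 44.8 to 46.7 CPM) and Slc25a31 lowest in 3xU (0.918; 0.539 against 0.923 to 0.957). At 42 °C Gata4 was highest in 2c4d (0.901; 1.26 against 0.812 to 0.856) and Hsp90aa1 in 1d2 (0.854; 705 against 472 to 506). Also at 42 °C, line 1d1 was highest in Pdgfra (0.939; 2.99 against 0.808 to 0.941) and Srgn (0.876; 1.45 against 0 to 0.18).

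Effects differed between groups by test in 4 comparisons. The DGCR8 line and the Drosha line differed in 1 gene at 48 h, Drosha itself, and in 30 genes at 96 h. The effect at 96 h differed from that at 24 h in 27 genes in the DGCR8 line and in 1880 in the Drosha line. The 30 and the 1880 rest on 1 Drosha 4OHT library at 96 h with a spread borrowed from other groups. The 30 went to 0 when only the compared groups were fitted, and the 27 to 0 without any of 6 libraries.

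Dgcr8 RNA rose in the line built to lose it. An exchange of control and 4OHT libraries is excluded: of the 108 genes called in both floxed lines at 48 h, 0 changed with opposite signs. Loss of Microprocessor cleavage of the hairpin in the Dgcr8 transcript fits, since Dgcr8 was called higher at 3 of 3 times in the Drosha line, where Dgcr8 is not the targeted gene. This account was found from the same data, so it is not settled by them. No other biological explanation was tested.

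The 4OHT libraries of the DGCR8 line at 96 h lay far apart. Replicate 1 held 27.1% of its counts in the mitochondrial ribosomal RNA mt-Rnr2 and replicate 2 held 9.55%. Replicate 1 being further along the response to 4OHT cannot be told apart: the replicate difference correlated across genes at -0.348, -0.248 and 0.364 with the Drosha effects at 24, 48 and 96 h, and at -0.228 and 0.0997 with the DGCR8 effects at 24 and 48 h. The value at 48 h in the Drosha line met the bound written beforehand to exclude it, but that bound was set aside after the values were seen, since early effects do not cover a later response and the only 96 h value, from a lone library that itself held 21.3% mt-Rnr2, goes the other way. A library property that also varies between untreated replicates cannot be told apart from other causes: in 8 of the other 10 floxed groups, the library with more mt-Rnr2 deviated the same way.

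Among 6 precipitates compared, only Drosha had large ratios at all 6 milk protein genes, with a median of 5.03 against 1.20 for DGCR8 with DSG. Uneven coverage of the parental input is excluded, since the Dicer precipitate over the same input had a median of 0.222 there. Reads from a library of another cell type cannot be told apart: 15 other lactation genes had a median at the 90.6 percentile of random lists. Drosha on RNA transcribed from these genes cannot be told apart either: in the 35 RNA libraries Csn3 reached 2.05 CPM and the other 5 genes at most 0.164, with Csn1s1 and Csn1s2a at 0, which goes against it, but no RNA library came from the Drosha-tagged cells. No biological explanation was tested that the labels give.

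Heat against 37 °C in the knockout lines was set against the other ways to split the same 8 libraries into 4 and 4. Over all splits, which ignore the cell lines, chance cannot be excluded for the number of genes: 3 of 35 splits called at least as many genes as the real 13, and the highest other split called 1206. That split and the next highest, which called 906, both parted 0 lines, so they set whole cell lines against each other and point to a structure of the samples; the 1206 split followed the Malat1 library set. Among the 8 splits that part the temperatures of all 4 lines, the other 7 all called 0 genes, although 1 of 8 is the least such a set can give. A separate fit of all 12 libraries with the cell line as a block called 1058 genes, and Hspa1a went from 0.738 to 1.56 CPM at 37 °C to 170 to 245 CPM at 42 °C in the 4 lines.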

How the results depend on the processing

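The added alternatives (fits by library set, heat-induced genes by block or by DESeq2, mitochondrial genes left out) were chosen only after the result was seen; all others were fixed before. Of 3328 values of single genes under all alternatives, 2528 kept their direction and side of the threshold, 733 lost their call, 40 gained one, 24 moved beyond their interval and 3 reversed. RLE normalisation kept 18 of 18 summary results, leaving out mitochondrial genes 15 of 15, and window means of 5 or 25 kept 3 of 3 each. Where a value moved, the cause was not tested, unless a cause is named. Not run were a window at gene starts, since the gene table gives no strand, and a line block for knockout against parental, which the design does not allow. No table compared depths.

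DESeq2 called 29 genes in the DGCR8 line at 24 h, 338 at 48 h and 104 for 96 h minus 24 h. It called 8 between the floxed lines at 48 h and 106 at 96 h, 31 for parental heat, 115 for knockout heat, 8 for their difference, and 779 and 753 for knockout against parental at 37 °C and 42 °C. For METTL3 it called 51634 windows over input (6387 higher, 45247 lower), 5571 windows after heat and 1583 genes after heat.

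Without a filter on low counts the DGCR8 line gave 56 genes at 24 h, 458 at 48 h and 269 for 96 h minus 24 h, the Drosha line 355 at 24 h and 933 at 48 h, and the difference between the lines 58 at 48 h and 427 at 96 h. Parental heat gave 22, knockout heat 46, their difference 24, and knockout against parental 383 at 37 °C and 380 at 42 °C. With a mean of at least 50 counts, DGCR8 at 24 h gave 8, Drosha at 24 h 14, the lines at 48 h 3 and knockout against parental at 42 °C 61.

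With only the compared groups fitted, fewer libraries set the spread. DGCR8 at 96 h then gave 0, its 96 h minus 24 h 0, Drosha at 24 h 748 and at 48 h 136, the lines at 96 h 0, knockout heat 13, and knockout against parental 4 at 37 °C and 1 at 42 °C. With replicate number as a block, DGCR8 gave 7 at 24 h, 76 at 48 h and 0 for 96 h minus 24 h. Drosha gave 54, 219 and 2057 at 24, 48 and 96 h and 243 for 96 h minus 24 h, and the lines at 96 h 1. With the cell line as a block parental heat gave 119, knockout heat 1058 and their difference 2; with H4 or H5 as a block, METTL3 heat gave 10268 windows and 7320 genes.

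With the Malat1 library set as a block parental heat gave 5, knockout heat 82, and knockout against parental 791 at 37 °C and 738 at 42 °C. Within the high set alone these were 0, 1, 0 and 0, and within the low set alone 0, 2, 0 and 0, with fewer libraries. Of 341 list tests 99 passed; an estimated correlation passed 21 and fry 61. Library size only gave 59 genes for METTL3 heat.

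Leaving out 1 library gave 1 to 4 genes for DGCR8 at 24 h, 15 to 27 at 48 h, 401 to 2953 at 96 h and 0 to 512 for 96 h minus 24 h. It gave 9 to 47 for Drosha at 24 h, 47 to 987 at 48 h, 3303 to 3484 at 96 h and 642 to 2364 for 96 h minus 24 h. The lines gave 1 to 1 at 48 h and 1 to 1876 at 96 h, parental heat 2 to 3, knockout heat 14 to 23, their difference 0 to 0, and knockout against parental 0 to 99 at 37 °C and 0 to 55 at 42 °C. METTL3 gave 40232 to 78878 windows over input, 351 to 1676 windows and 0 to 9 genes after heat, and 0.283 to 0.305 in the top quartile.

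For the top expression quartile, scaling to windows without a gene moved DGCR8 with formaldehyde from 0.062 to -0.243, which reversed it, DGCR8 with DSG from 0.447 to 0.040, Dicer from -0.047 to -0.079, Drosha from 0.140 to 0.037, METTL3 from 0.297 to 0.069, DGCR8 knockout over wild type from -0.050 to -0.055 and DGCR8 42 °C over 37 °C from -0.530 to -0.948. It moved the heat shock core list from 2.044 to 1.627 and the heat-induced genes to 3.758 for DGCR8 and 8.307 for METTL3 H4. A minimum of 100 counts gave -0.027 for formaldehyde, reversed, 0.414 for DSG, 0.008 for Drosha, -0.536 for 42 °C over 37 °C and 0.148 for METTL3; a pseudocount of 5 gave 0.431 for DSG, 0.128 for Drosha and -0.500 for 42 °C over 37 °C. Heat-induced genes called with the cell line as a block reversed to -0.349 for DGCR8, -0.349 for H4 and -0.123 for H5, and those called by DESeq2 to -0.769, -0.536 and -0.043. Among single genes, Drosha in the DGCR8 line, not called either way, ran from -0.15 to 0.09 at 48 h, turning without control replicate 2 (adjusted p = 0.922), and from -0.09 to 0.24 at 96 h, turning without 4OHT replicate 2 (adjusted p = 0.692), and Hspa8 for DGCR8 42 °C over 37 °C turned to -0.024 when scaled to windows without a gene.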

Other observations

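Genes with the highest DGCR8 ratios were followed across precipitates. The top 1% by DGCR8 with DSG were 286 genes, and their median log2 ratio was 0.741 in the wild type DGCR8 precipitate, with 264 of 273 above 0, and 1.68 with Drosha against -0.233 with Dicer. They held microRNA and small nucleolar RNA genes, but also many olfactory receptor genes, such as Olfr729 at 2.86 and Olfr1052 at 2.52. Windows without a gene lay at 0.407 in this library. The set is therefore not a list of DGCR8 targets. In the Mettl3 knockout precipitate over the wild type one their median was -0.399, with 214 of 281 below 0, against -0.014 for other genes. After heat the DGCR8 ratio of 42 °C over 37 °C had a median of -0.850 in them, with 186 of 286 below 0.

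In the DGCR8 line at 96 h Hspa5, the main chaperone of the endoplasmic reticulum, rose by 0.62 ± 0.10 (adjusted p = 0.00396), while Chac1 and Trib3, targets of Atf4, fell by 1.39 ± 0.22 and 0.94 ± 0.15 (adjusted p = 0.00324 and 0.00288; n = 2 and 2). In the Drosha line at 96 h Dnajb9, a co-chaperone of Hspa5, rose by 1.34 ± 0.17 (adjusted p = 0.000109), and Chac1 and Trib3 fell by 1.87 ± 0.30 and 1.43 ± 0.19 (adjusted p = 0.000605 and 0.000201; n = 1 and 2). The unfolded protein response list was not called in either line at 96 h (camera adjusted p = 0.656 and 0.367). Histone genes were lower in 48 of 54 in the DGCR8 line (camera adjusted p = 5.5e-07), a call lost when the correlation was estimated (adjusted p = 0.215 with an estimated correlation), and in 52 of 55 in the Drosha line (camera adjusted p = 6.79e-07; adjusted p = 0.501 with an estimated correlation).

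A set of 4 hypotheses joined the tables, and all of their tests were written down before their values were seen. That the METTL3 precipitate follows the change of RNA after heat could not be decided. Without the heat shock chaperone list, Spearman rho was -0.0424 across genes, which are not independent replicates. It met the bound written beforehand to exclude the hypothesis. But few genes had a parental RNA change that could be called. The edgeR fit without a block, which ignores the pairing by line, gave 425 genes below an unadjusted p of 0.05, against 782 by chance. With the cell line as a block 69 genes rose and 50 fell, of 15635 tested. A rho across all genes therefore cannot show whether the precipitate followed RNA at the genes whose RNA changed. That DGCR8 and METTL3 move between the same genes after heat fits (rho = 0.749 across genes, without the heat shock chaperone list). Expression was not held fixed in this rho. Relative to windows without a gene, the top expression quartile fell in all 3 ratios: -0.948 for DGCR8, -0.429 for H4 and -0.257 for H5. A change that goes with expression in every precipitate was therefore not separated from movement between the same genes. That DGCR8 is lost in the knockout where METTL3 is enriched cannot be told. The partial rho of 0.14 across genes, given the DGCR8 ratio, met the bound written beforehand to exclude it. That bound was set aside after the values were seen, since the plain rho was -0.0914, the sign turned only with a ratio that itself followed METTL3 (rho = 0.666), and there was 1 library of each kind. That transcripts held by DGCR8 rise when it is lost met its prediction, but the test does not show that DGCR8 held them. The 182 genes called higher at 48 h, measured by ChIP and not on the miRNA host list, had a median DGCR8 ratio of 0.193. Random lists had 0.0296, and 99.89% of them lay below. Windows without a gene lay higher in the same library, at 0.407. Genes that fell were not compared, and hairpin genes outside the host list were not removed.

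The heat RNA libraries fell into 2 sets by Malat1, a nuclear long noncoding RNA: parental 1, 1d1 and 3xU at 3649 to 8474 CPM, and parental 2, 1d2 and 2c4d at 1219 to 2155 CPM. The labels name no such set, but their sample numbers follow it: all libraries of the high set are numbered before all those of the low set. What the sets stand for was not tested.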
